A study of Arabidopsis thaliana with 14 samples.

How the data were processed

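Gene expression was measured in Arabidopsis thaliana seeds of ecotype Ws-0 at the linear-cotyledon stage, when the embryo was 175 ± 11 µm long. Siliques of 1.6 to 1.9 cm were taken from plants aged 38 to 46 days. Per the labels, tissue was fixed in ethanol and acetic acid and embedded in paraffin, and compartments were cut from sections with a laser. From each sample 2 to 5 ng of RNA was amplified, labelled with biotin and hybridised to an Affymetrix ATH1 array. There were 14 arrays in 7 groups of 2 biological replicates: embryo proper, micropylar endosperm, cellularized endosperm, chalazal endosperm, chalazal seed coat, general seed coat and whole seeds.

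The labels conflict at 2 points. A description field of the 2 micropylar endosperm arrays speaks of whole seeds, while their titles and source fields name micropylar endosperm, and they were used as titled. The design text of the series lists micropylar endosperm more than once and leaves out chalazal endosperm, which the sample titles name. The labels give no scan date or batch, and do not say which plants or seeds gave each replicate, so p-values measure only the spread between these samples. The micropylar and whole-seed arrays were deposited with later identifiers than the other 10 arrays, and whether they were prepared apart is not stated.

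The deposited values are signal intensity per probe set, on a linear scale and 1 colour. The authors scaled each array, and the mean over all 22810 probe sets after leaving out the lowest and highest 2% was 500 on each of the 14 arrays. The labels name GCOS as the processing software, with no version. Array medians ran from 106.6 to 183.1. Signals of arrays are not counts, so the number of arrays limits the precision.

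Values were analysed as log2(value + 16). The 64 control probe sets were left out, and 15951 of the other 22746 were tested, those at or above their array median on at least 2 arrays. Gene names came from the platform's table of probe sets and genes, in which 13513 probe sets name 1 gene, 503 several and 8794 none. A symbol other than the locus code was given for 1580 of these, of which 1204 were tested, and 13436 matched a locus in the RefSeq gene table. The genome build is not stated and no positions are given.

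Fits used limma 3.58.1 in R 4.3.3 with 1 mean per group over all 14 arrays, leaving 7 residual degrees of freedom, and moderated variances with a trend on signal level. There were 13 comparisons. Each of the 6 compartments was set against the mean of the other 5, and 4 pairs of compartments were compared directly. The former 6 comparisons share the same group means, so a low level in 1 compartment raises the change of the others. Their results are not independent. Whole seeds were set against the mean of the 6 compartments. In 2 region comparisons the 2 arrays of a compartment were averaged first, so that the compartment was the replicate. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison and a change of at least 2-fold. All p-values are two-sided.

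Genes to name were picked by a rule. Among calls in which both arrays of a compartment lay beyond every array it was compared with, and whose probe set named 1 gene with a symbol, these were the 10 with the largest rise and the 5 with the largest fall, or 10 each way in the 4 pairs. Members of gene lists were named besides. In 74 of 182 results for genes picked by the rule the lowest of the 6 compartment means lay below the pseudocount of 16. Where that compartment is part of the comparison, the size of the change depends on the pseudocount. In the 4 pairs it can lie outside, as for GH9B5 between the seed coat parts, with -3.85 and -3.52 at pseudocounts of 1 and 64. The comparisons, the naming rule, 16 gene lists and all alternatives but those named last were fixed before the data were examined. The lists covered embryo patterning, endosperm regulators, the flavonoid pathway, seed coat mucilage, ovule and seed coat identity, vascular tissue, nutrient transporters, storage and oil bodies, fatty acid synthesis, photosynthesis, cell division, cytokinin, auxin, gibberellin and abscisic acid, cell wall loosening, and ribosomal proteins. Of these, 11 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over 143 tests, and again with an estimated correlation. Most listed genes had no probe set naming them alone, so each list stands for a small part of its pathway. Of 50 photosynthesis symbols 9 genes were named on the array, of 49 for embryo patterning 7 and of 52 for cell division 4. For the flavonoid pathway these were 4 of 34, for cell wall loosening 10 of 43 and for vascular tissue 2 of 30. A missing member is no sign of absent expression. The median, the mean and the test of a list differed in sign in 21 of the 143 tests, 0 of which passed. A further 27 sets, made of gene families with 6 or more tested genes and of organelle genes, were added after the data were seen and adjusted over 351 tests.

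The pipeline was tested on simulated data with 15951 probe sets. For the embryo proper against the other compartments it called 9% of 2-fold, 64.2% of 4-fold and 78.8% of 8-fold changes, and 2 of 15751 unchanged probe sets. For the chalazal against the general seed coat these were 3%, 32.8% and 57.6%, with 1 of 15751 unchanged. In simulations of both region comparisons 0% of 8-fold changes were called. The spread between compartments was there taken from the real means, so real region differences counted as noise. With 15751 of 15951 probe sets unchanged, the simulations held far fewer changes than the real single-compartment comparisons had calls. This makes the adjusted p stricter, so the recovered shares do not directly measure power in the real data.

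Alternatives were another pseudocount (1 or 64), no filter or a stricter filter, quantile normalization, scaling to equal medians, variances without a trend, the replicate number as a block, no fold threshold, whole seeds left out of the fit, only the compared arrays in the fit, contrasts of group means for the regions, an estimated correlation for the lists, and each array left out in turn. Leaving out an array leaves its group with 1 array, which is assumed to vary like the other groups. Comparisons without the chalazal or the micropylar endosperm were added after the data were seen.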

Results

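Transcript levels were measured on 14 arrays, 2 each for the embryo proper, 3 parts of the endosperm (micropylar, cellularized and chalazal), the chalazal seed coat, the general seed coat and whole seeds. The endosperm is the tissue that feeds the embryo, and the seed coat is maternal. The chalazal pole is where the mother plant's vascular strand ends, and the micropylar pole surrounds the young embryo. Levels are array signal intensities, given as the mean ± SD of 2 arrays. Changes are log2 fold changes with their SE, and each gene named for a rise or fall outside a gene list had both arrays of its compartment beyond every array it was compared with.

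Replicate arrays correlated across probe sets with Pearson r from 0.851 in the chalazal seed coat to 0.914 in the embryo proper, where probe sets are not independent replicates. The micropylar and cellularized endosperm were close, with a mean r of 0.815. The chalazal endosperm stood apart, with a mean r of 0.539 to the cellularized endosperm, 0.48 to the micropylar endosperm and 0.582 to the chalazal seed coat. The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity, was 13.65 and 8.34 on the chalazal endosperm arrays, 6.42 and 3.59 on the micropylar arrays and 3.2 and 2.72 on the whole-seed arrays. It lay between 5.33 and 7.87 on the others. The other 2 control genes did not set the chalazal endosperm apart, with ubiquitin ratios of 8.63 and 8.72 where all arrays ran from 5.36 to 12.02, and actin ratios of 14.79 and 9.01 where they ran up to 36.81 on embryo proper replicate 1.

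**Figure D1:**
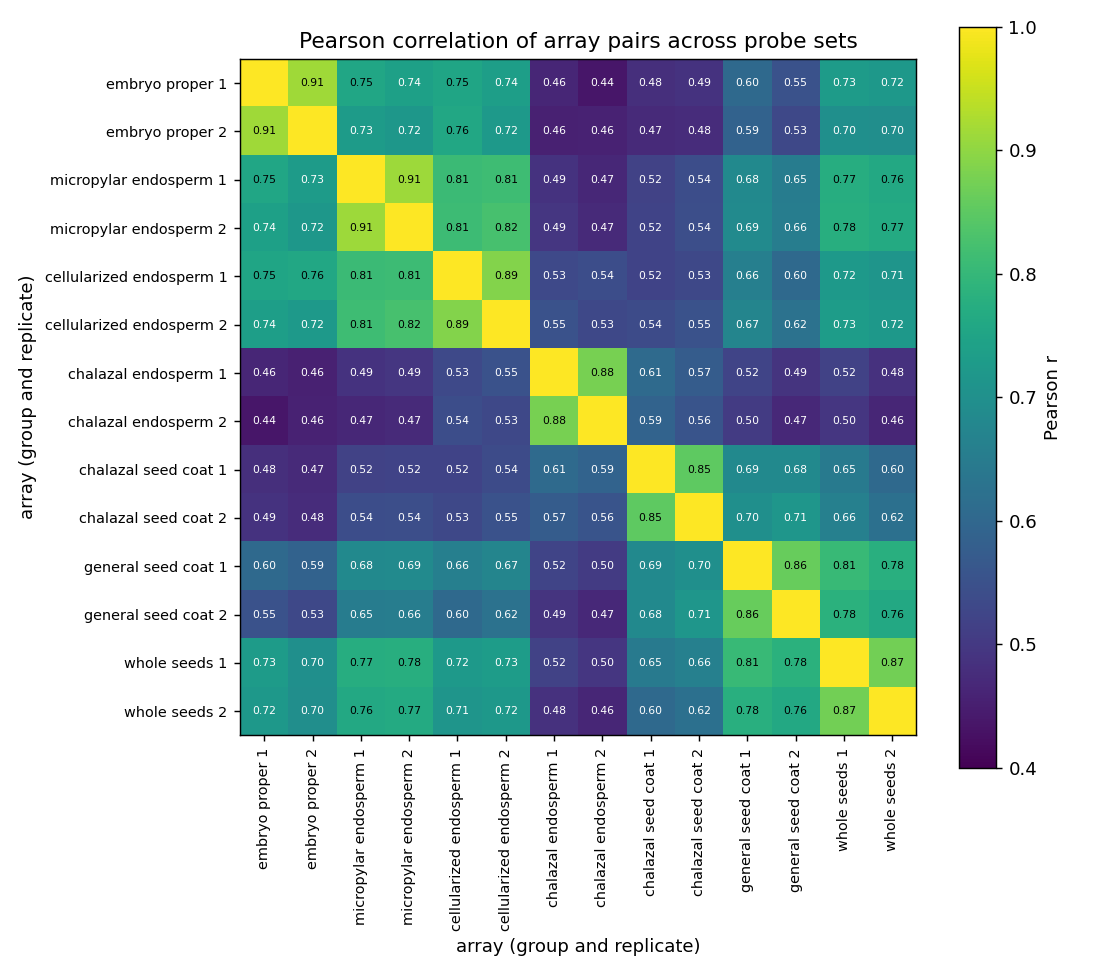
Pearson correlation across probe sets of each pair of the 14 arrays, with arrays in rows and columns and r as colour and number. Replicate pairs lie between 0.851 and 0.914, and pairs of chalazal endosperm with micropylar endosperm have a mean of 0.48.

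The embryo proper was set against the other 5 compartments to find genes expressed there. YAB3, a YABBY transcription factor of abaxial cell fate in cotyledons and leaves, reached 2409 ± 110 (n = 2) in the embryo and at most 49.7 in the other compartments, a rise of 6.14 (SE 0.64, adjusted p = 1.89e-06). STOMAGEN, a secreted peptide that promotes stomata, rose by 4.17 (SE 0.83, adjusted p = 0.00102), and GH3.3, which conjugates auxin to amino acids, by 4.15 (SE 0.69, adjusted p = 0.000203). GSTU27, SBT1.3, ATLP-1, BZIP61, TET15, EXPA15 and ATMYC1 rose by 5.57 to 4.03. DFR, a reductase of anthocyanin and tannin synthesis, fell by 5.56 (SE 0.34, adjusted p = 3.62e-09), and UGT84B1, DELTA-VPE, bZIP44 and AER had changes of -4.98 to -4.49. In the list of embryo patterning genes 4 of 6 tested members rose, and 6 when adjusted over the list alone: YAB3, YAB5 (3.39), BBM (2.64) and LHW (2.38), while JKD at 1.63 and PHV at 1.11 did not pass. The list's adjusted p was 0.00192 by camera, but 0.08 with an estimated correlation and 0.052 with a stricter filter. All 9 tested photosynthesis genes rose, also when adjusted over the list alone (9), from PSAN (2.90), a photosystem I subunit, and RCA (2.14), rubisco activase, to PSBY (1.13), whose call ended without the chalazal endosperm (adjusted p = 0.0555). The list had adjusted p = 6.96e-07 and 0.0151 with an estimated correlation. Low levels in other compartments add to such rises. PRK stood at 12800 in the embryo proper, 11896 in the cellularized and 530.4 in the chalazal endosperm, and RCA at 2266, 336.9 and 123.9. The 4 cell division genes, PRL, which encodes a replication licensing protein (2.53), and 3 genes of Aurora kinases, which act in mitosis, all rose, 4 adjusted over the list alone, with adjusted p = 0.0218, and adjusted p = 0.184 with an estimated correlation. In the flavonoid list DFR and BAN, an anthocyanidin reductase (-3.67), fell, 2 of 4 members by either adjustment (2 adjusted over the list alone). That list's adjusted p was 0.0464, against 0.468 with an estimated correlation, 0.0741 with a pseudocount of 64, 0.0956 with a stricter filter and 0.0562 with the replicate block. The auxin list did not pass (adjusted p = 0.407), with GH3.3 and GH3.17 called higher, 2 of 4 members, also 2 adjusted over the list alone. The call of GH3.17 ended under 5 alternatives (adjusted p of 0.0568 to 0.334), among them leaving out embryo proper replicate 1 (0.0925) or 2 (0.334) and micropylar endosperm replicate 1 (0.0568). PGY1, the only tested ribosomal protein gene of its list, rose by 1.26 (SE 0.21, adjusted p = 0.00022). In the fatty acid list FATB, an acyl-ACP thioesterase, fell by 1.45 (SE 0.30, adjusted p = 0.00133) and accD was at 0.33. CLE41, the only tested vascular gene, rose by 2.09 (SE 0.72, adjusted p = 0.0355). In all, limma called 4537 probe sets, 2406 higher and 2131 lower. Without embryo proper replicate 1 there were 2356 calls and without replicate 2 there were 2507. Calls of BBM (adjusted p = 0.0596 and 0.0526), AUR1 (0.131 and 0.0769) and AUR3 (0.0658 and 0.373) ended without replicate 1 and without replicate 2, and that of AUR2 without replicate 2 (0.0746). That of CLE41 ended without either (0.226 and 0.153), without cellularized endosperm replicate 1 (0.052), without the micropylar endosperm (0.0663) and with a pseudocount of 1 (0.0533), and that of AUR3 also without replicate 1 of the cellularized (0.0517) or micropylar endosperm (0.0508).

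**Figure D2:**
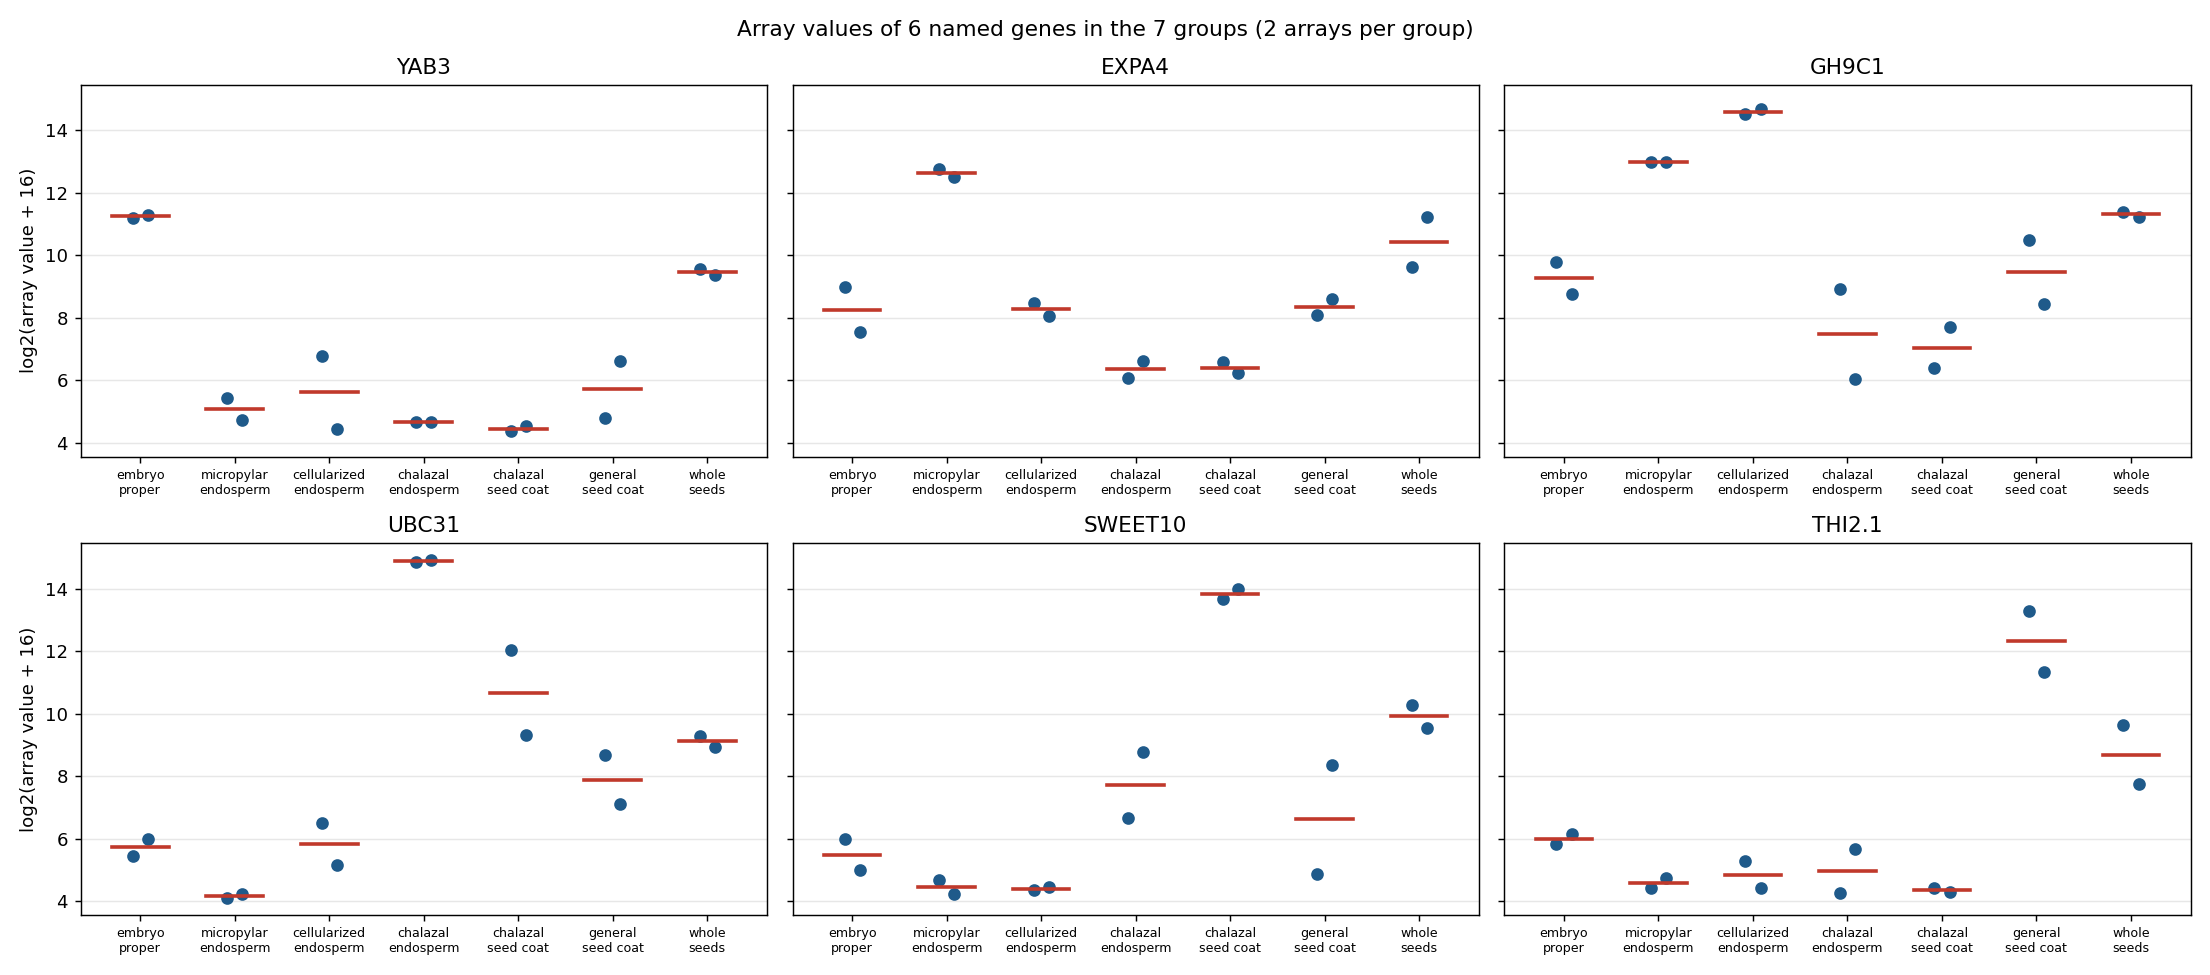
Array values of YAB3, EXPA4, GH9C1, UBC31, SWEET10 and THI2.1 on a log2 axis (value + 16) in the 7 groups, with a point per array and a bar at the mean of 2 arrays. Each gene is highest in a different compartment, as for SWEET10 in the chalazal seed coat and UBC31 in the chalazal endosperm.

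In the micropylar endosperm, set against the other 5 compartments, EXPA4, an expansin that loosens cell walls, reached 6420 ± 774 (n = 2) against at most 329.7 in the other compartments, a rise of 5.12 (SE 0.46, adjusted p = 9.7e-07). XTH32, a xyloglucan endotransglucosylase, rose by 4.09 (SE 0.69, adjusted p = 0.00039), AMY1, an alpha-amylase, by 4.09 (SE 0.46, adjusted p = 6.57e-06), and SDT, which adds sinapoyl groups to spermidine, by 4.85 (SE 0.62, adjusted p = 2.85e-05). LBD16, ROXY2, GSTU18, AtVEX1, BGLU29 and NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, rose by 4.35 to 3.55. UBC31, a ubiquitin-conjugating enzyme, fell by 4.83 (SE 0.59, adjusted p = 1.6e-05) and ZIP6, a metal transporter, fell by 3.85 (SE 0.43, adjusted p = 6.3e-06). All 9 photosynthesis genes rose (9 adjusted over the list alone), from PSAN (3.07) and PSAE-1 (2.57) to ATPC1 (1.74) and PSBW (1.54), with adjusted p = 3.76e-10, and 0.0139 with an estimated correlation. The GAPDH ratios of these arrays were 6.42 and 3.59. Among cell wall loosening genes 4 of 7 rose, also 4 adjusted over the list alone: EXPA4, EXPA9 (3.51), EXPB1 (2.92) and EXPA20 (2.69), while EXPB3 at -0.33 and ADPG1 at -0.46 did not pass. The adjusted p was 0.00843, and 0.111 with an estimated correlation. In the cytokinin list ARR15, a response regulator, rose by 3.54, 1 of 3 members (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.272). Neither did the gibberellin and abscisic acid list (adjusted p = 0.527), in which 0 of 3 members were called, 0 adjusted over the list alone. limma called 2878 probe sets, 1794 higher and 1084 lower. Calls numbered 1146 without micropylar endosperm replicate 1 and 1423 without replicate 2, and ended for EXPA9 (adjusted p = 0.113) and PSAN (0.0545) without replicate 1 and for EXPA20 (0.0762) and ATPC1 (0.0509) without replicate 2. The other 3 of the largest falls also lost their call: PLIM2a (-3.36) without either replicate (0.0591 and 0.0525), HLL (-2.63) without replicate 2 (0.202) and GSTU15 (-2.61) without the chalazal endosperm (0.0577).

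The cellularized endosperm was set against the other 5 compartments to find genes expressed there. GH9C1, a family 9 endoglucanase, reached 24728 ± 2045 (n = 2), a rise of 5.34 (SE 0.57, adjusted p = 4.42e-06), and the related GH9B8 rose by 4.21 (SE 0.45, adjusted p = 4.89e-06). SWEET11, a sucrose exporter, rose by 4.49 (SE 0.51, adjusted p = 8.17e-06), and SHT, a spermidine hydroxycinnamoyl transferase, by 3.97 (SE 0.54, adjusted p = 5e-05). For each of these genes the next highest compartment was the micropylar endosperm. Mean levels there were 8015 for GH9C1, 2376 for GH9B8, 5017 for SWEET11 and 474.7 for SHT. In the cellularized part GH9B8, SWEET11 and SHT had 3504, 11210 and 1411. The changes given are thus larger than those between the 2 parts. IQD16, UGT76E2, BGLU44, MGL and TUB1, a beta-tubulin, rose by 4.16 to 3.29, and GH9B18 by 3.40, a call that ended without cellularized endosperm replicate 2 (adjusted p = 0.0578). TBL45 (-4.62), LSH5, GH3.9, BRH1 and ARA12 (-3.06) were lower. Of the transporter list, SWEET11 and SAG29 (2.07), also known as SWEET15, rose and SWEET10 fell by 3.22, the same 3 members adjusted over the list alone (2 higher, 1 lower), and the list did not pass (adjusted p = 0.251). The 4 cell division genes rose, AUR2 by 2.52 and PRL by 1.74 among them (4 adjusted over the list alone), with adjusted p = 0.00518, and adjusted p = 0.113 with an estimated correlation. OLEO3, an oleosin of oil bodies (2.98), and EEL, a bZIP factor of seed maturation (1.88), rose in the storage list, 2 of 3 members (2 adjusted over the list alone), while BZIP53 stood at -0.24. That list's adjusted p was 0.0218, against 0.262 with an estimated correlation and 0.0578 with a stricter filter. Of the photosynthesis genes 3 of 9 rose, PRK (1.99), PSAN (1.90) and ATPC1 (1.43), of which PSAN lost its call under 17 alternatives, with adjusted p of 0.0571 to 0.354. RCA stood at -1.01, with 3 higher and 1 lower adjusted over the list alone. That list had adjusted p = 0.00388, and 0.0883 with an estimated correlation. limma called 2637 probe sets, 1305 higher and 1332 lower, against 1535 and 1171 with equal medians and 1246 and 1040 with quantile normalization. Calls numbered 1315 without cellularized endosperm replicate 1 and 1404 without replicate 2, and ended for PSAN (adjusted p = 0.354 and 0.131) without either, for ATPC1 without replicate 1 (0.053) and without the chalazal endosperm (0.0552), for SWEET10 without replicate 1 (0.0544) and for PRL without replicate 2 (0.0914). AUR1 lost its call under 7 alternatives, with adjusted p up to 0.233 or a change under 2-fold, among them leaving out either cellularized array, embryo proper replicate 2, chalazal endosperm replicate 1 (1.00) or general seed coat replicate 2 (0.94). AUR3 lost it under 5 (adjusted p of 0.0555 to 0.347), among them either cellularized array, embryo proper replicate 1 (0.0621) and micropylar endosperm replicate 1 (0.0555).

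The chalazal endosperm had the most calls of the 6 compartments set against the other 5. UBC31 reached 30093 ± 829 (n = 2), a rise of 8.02 (SE 0.59, adjusted p = 1.2e-08). The response regulators RR23 and RR19, of the family that relays cytokinin signals, rose by 6.61 (SE 0.68, adjusted p = 5.55e-07) and 6.22 (SE 0.80, adjusted p = 7.45e-06). CYP79A2, a cytochrome P450 that makes phenylacetaldoxime, rose by 6.42 (SE 0.74, adjusted p = 2.18e-06), and the MADS-box gene AGL33 by 5.95 (SE 0.84, adjusted p = 2.12e-05). SBT4.13, GSTU15, SK16, NGA4 and MMP, a matrix metalloproteinase, rose by 7.28 to 5.07. BGLU29 fell by 6.03 (SE 0.35, adjusted p = 1.47e-09), and TRM20, FMO, COS1 and iqd32 changed by -5.73 to -5.08. All 9 photosynthesis genes fell (9 adjusted over the list alone), from PSBW (-1.73) and PSBY (-2.52) to PRK (-3.39) and PSAN (-4.21), with adjusted p = 2.23e-07, and 0.0139 with an estimated correlation. GAPDH ratios were 13.65 and 8.34 on these arrays, the highest, but ubiquitin and actin ratios were not. The cytokinin list did not pass (adjusted p = 0.441): RR16 fell by 1.59, 1 of 3 members, and 3 fell adjusted over the list alone, with ARR15 at -1.47 and UGT76C2 at -1.09. In the list of endosperm regulators MPC (2.53) and AGL91 (2.30) rose, 2 of 4 members (2 adjusted over the list alone), while AGL23 at 1.38 and IKU1 at -0.88 did not pass, nor did the list (adjusted p = 0.395). limma called 6175 probe sets, 2516 higher and 3659 lower. With arrays scaled to equal medians these were 3227 and 3175, a share of higher calls of 50.4% against 40.7% as deposited and 44.1% with quantile normalization. The calls of MPC (adjusted p = 0.0652) and RR16 (0.418) ended without chalazal endosperm replicate 2, and that of AGL91 without replicate 1 (0.0566) and without replicate 2 (0.0977).

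**Figure D3:**
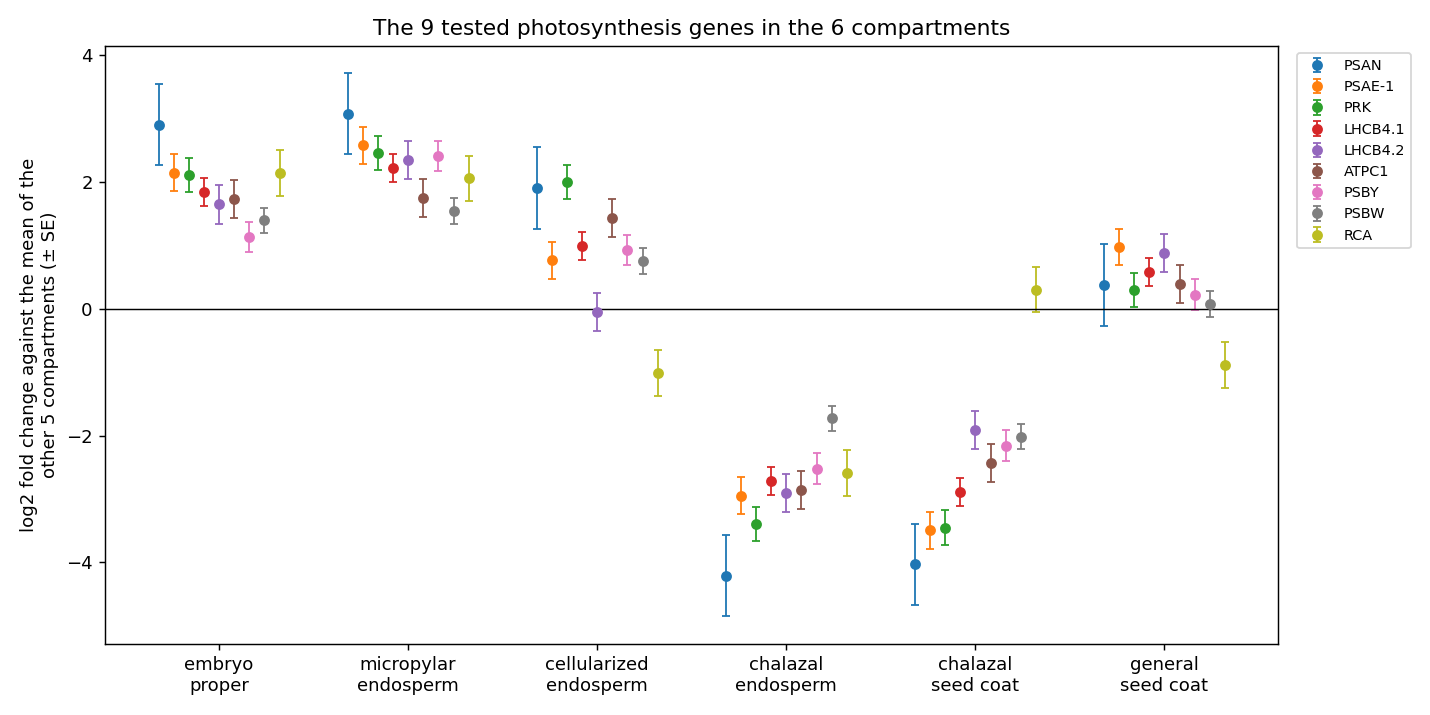
Log2 fold change of the 9 tested photosynthesis genes in each compartment against the mean of the other 5, with bars of 1 SE from the fit over 14 arrays. All 9 lie above 0 in the embryo proper and micropylar endosperm and below 0 in the chalazal endosperm, and 8 were called lower in the chalazal seed coat.

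In the chalazal seed coat, set against the other 5 compartments, SWEET10, a sugar exporter, reached 14508 ± 2172 (n = 2) against at most 252.5 elsewhere among the compartments, a rise of 8.09 (SE 0.71, adjusted p = 1.75e-07). ZIP6 rose by 5.33 (SE 0.43, adjusted p = 6.87e-08), GTR2, a glucosinolate transporter, by 5.12 (SE 0.68, adjusted p = 1.85e-05), and ATSPS4F, a sucrose-phosphate synthase, by 6.60 (SE 0.52, adjusted p = 5.63e-08). HAT2, an auxin-induced homeodomain gene, and RR22, a response regulator, rose by 7.35 (SE 0.78, adjusted p = 1.49e-06) and 6.67 (SE 0.44, adjusted p = 9.69e-09). LCR68, scpl31, CYP718 and PME61 rose by 6.44 to 5.28. The nutrient transporter list did not pass (adjusted p = 0.633), with SWEET10 higher, SAG29 lower at -1.68 and SWEET11 at 0.59 not called (1 and 1 also adjusted over the list alone). OLEO3 fell by 6.95 (SE 0.28, adjusted p = 3.84e-11), and PDF2.1, AUR2, CaS and 3xHMG-box2, a mitotic chromosome protein, changed by -4.79 to -3.42. Of the photosynthesis genes 8 of 9 fell (8 adjusted over the list alone), PSAN by -4.03 and PSAE-1 by -3.49, while RCA stood at 0.30, with adjusted p = 3.94e-08, and 0.0139 with an estimated correlation. The 4 cell division genes fell (4 adjusted over the list alone), from PRL (-1.52) to AUR2 (-4.53), with adjusted p = 0.00192, and adjusted p = 0.0883 with an estimated correlation. DFR (4.99) and BAN (3.89) rose while UGT78D2 fell by 1.31 in the flavonoid list, 2 higher and 1 lower of 4 by either adjustment (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.241). CYP78A9, a P450 of ovule integument growth and the only tested gene of the ovule list, rose by 4.64 (SE 0.67, adjusted p = 4.71e-05). limma called 4182 probe sets, 2164 higher and 2018 lower, against 2048 and 2128 with equal medians and 2042 and 2159 with quantile normalization. Without chalazal seed coat replicate 2 the calls of PRL (adjusted p = 0.177), AUR3 (0.0988) and UGT78D2 (0.216) ended.

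In the general seed coat, set against the other 5 compartments, THI2.1, a thionin, reached 6208 ± 5131 (n = 2) against at most 47.9 in the other compartments, a rise of 7.36 (SE 0.65, adjusted p = 3.21e-07). JMT, which methylates jasmonic acid, rose by 5.72 (SE 0.51, adjusted p = 3.35e-07), GH9B5, an endoglucanase, by 6.14 (SE 0.52, adjusted p = 2.09e-07), and UGT73B1, a flavonoid glucosyltransferase, by 5.46. TBL38, of the trichome birefringence-like family of wall acetylation genes, reached 27684 ± 7456 (n = 2), a rise of 6.98 (SE 0.51, adjusted p = 4.25e-08). GILT, ATPMEPCRD, scpl35, RING1 and scpl20 rose by 6.43 to 4.55. CHR23, CYP71B5 and SWI3A changed by -3.29 to -2.95, ZYP1b by -2.57 and WES1 by -2.48. The call of ZYP1b ended without general seed coat replicate 1 (adjusted p = 0.0899) and that of WES1 without replicate 1 (0.0611) and without replicate 2 (0.0579). AT3G50990, which encodes the peroxidase PER36 of mucilage release and is the only tested member of the mucilage list, rose by 5.63 (SE 0.61, adjusted p = 3.04e-06). In the flavonoid list DFR (3.68) and BAN (3.50) rose, 2 of 4 members (2 adjusted over the list alone), and the list did not pass (adjusted p = 0.251). In the cell wall loosening list 0 of 7 members rose and EXPA15 fell by 2.03 (1 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.475). limma called 2560 probe sets, 1652 higher and 908 lower. Calls numbered 1329 without general seed coat replicate 2, and that of EXPA15 ended without replicate 1 (adjusted p = 0.0866) and without replicate 2 (0.103). The share of calls that were higher was 64.5% as deposited, 54.4% with arrays scaled to equal medians and 59.2% with quantile normalization.

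The 2 seed coat parts were compared to find genes of the chalazal end. SWEET10 rose by 7.21 in the chalazal part (SE 0.91, adjusted p = 4.45e-05), or 7.76 and 6.41 with pseudocounts of 1 and 64, as the general seed coat arrays stood at 13.4 and 308.7. LCR68, a defensin-like gene, rose by 6.76 (SE 0.65, adjusted p = 3.33e-06). LHW, a basic helix-loop-helix factor of vascular development, rose by 4.92 (SE 0.53, adjusted p = 1.02e-05), from 59.8 ± 29.1 to 2188 ± 68.3 (n = 2 each). HAT2, GTR2, ATSPS4F, CYP718, TET5, CYP78A9 and scpl31 were higher by 6.51 to 4.96. THI2.1 fell by 7.96 (SE 0.84, adjusted p = 8.25e-06), to 4.29 ± 1.3 (n = 2) in the chalazal part, below the pseudocount. Its change was -9.92 and -6.23 with pseudocounts of 1 and 64. OLEO3 fell by 7.17 (SE 0.36, adjusted p = 1.84e-09), while NCRK, ATPMEPCRD, PDF2.1, CR4, UPP, scpl48, CDI and GH9B5 changed by -5.87 to -3.77. Photosynthesis genes fell in 8 of 9 cases (8 adjusted over the list alone), PSAE-1 by -3.72 and PRK by -3.11, while RCA stood at 0.99, with adjusted p = 3.22e-08, and 0.0139 with an estimated correlation. The call of PSAN ended without general seed coat replicate 1 (adjusted p = 0.0513). limma called 2331 probe sets, 1004 higher and 1327 lower, and 1461 when only the 4 compared arrays were in the fit.

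Within the endosperm, the chalazal part was compared with the cellularized part. UBC31 rose by 9.05 (SE 0.76, adjusted p = 7.83e-08), and RR22, RR19 and RR23 rose by 5.57, 6.60 and 6.28. RR22 stood at 2187 ± 952 here and at 18442 ± 4084 in the chalazal seed coat (n = 2 each). SBT4.13, CYP79A2, SK16, GSTU15, AGL33 and FOLB1, a folate synthesis gene, rose by 7.45 to 5.58. SWEET11 fell by 7.46 (SE 0.65, adjusted p = 1.31e-07), from 11210 ± 2948 to 74.9 ± 92.9 (n = 2 each), with changes of -8.18 and -6.50 under pseudocounts of 1 and 64. GH9C1 fell by 7.10 (SE 0.73, adjusted p = 8.75e-07). BGLU29, BGLU44, IQD16, UGT76E2, OLEO3, SCPL45, GH9B8 and SBTI1.1 changed by -7.16 to -6.29. The 9 photosynthesis genes fell (9 adjusted over the list alone), with PSAN at -5.09 and PRK at -4.48, adjusted p = 1.83e-07, and 0.0139 with an estimated correlation, on arrays with GAPDH ratios of 13.65 and 8.34 against 7.16 and 5.78, and ubiquitin ratios of 8.63 and 8.72 against 10.25 and 8.88. The call of RCA ended under 8 alternatives, with adjusted p of 0.05 to 0.21, among them leaving out cellularized replicate 1 (0.05) or 2 (0.21) and chalazal endosperm replicate 1 (0.0634) or 2 (0.16). limma called 5119 probe sets, 2249 higher and 2870 lower.

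The micropylar and cellularized endosperm differed least among the 4 pairs by number of calls. TBL45 rose from 4.08 ± 1.2 in the cellularized to 1309 ± 447 (n = 2 each) in the micropylar part (adjusted p = 3.23e-05). The lower level is below the pseudocount, which sets the size of the change, 7.99 with a pseudocount of 1 and 4.29 with 64. SIM, an inhibitor of cyclin-dependent kinases that promotes endoreduplication, rose by 4.84 (SE 0.86, adjusted p = 0.00253). The expansins EXPA20 and EXPA4 rose by 4.70 (SE 0.65, adjusted p = 0.00043) and 4.38 (SE 0.60, adjusted p = 0.000364), and ALDH11A3 by 3.63 (SE 0.55, adjusted p = 0.00083). GH9B18 fell by 4.54 (SE 0.87, adjusted p = 0.00427), scpl50 fell by 3.49 (SE 0.54, adjusted p = 0.000932) and ATERDJ3B fell by 2.56 (SE 0.31, adjusted p = 0.000193). Cell wall loosening genes rose in 3 of 7 cases, and 4 adjusted over the list alone, with EXPB3 at -0.52 among those that did not pass, adjusted p = 0.00192, and adjusted p = 0.08 with an estimated correlation. Of the photosynthesis genes 5 of 9 rose (5 adjusted over the list alone), RCA by 2.56 and LHCB4.2 by 1.99. PRK stood at 0.38 and ATPC1 at 0.26. The list had adjusted p = 0.000158 by camera, and 0.0453 with an estimated correlation. Ubiquitin ratios were 6.03 and 7.5 on the micropylar arrays against 10.25 and 8.88 on the cellularized ones. GAPDH ratios (6.42 and 3.59 against 7.16 and 5.78) and actin ratios (23.59 and 10.8 against 19.51 and 11.97) overlapped. BAN (2.72) and DFR (2.46) rose in the flavonoid list, 2 of 4 members (2 adjusted over the list alone), with adjusted p = 0.0234, against 0.437 with an estimated correlation and 0.0512 with a pseudocount of 64. PRL fell by 1.71 in the cell division list, 1 of 4 members, and 2 fell adjusted over the list alone, with adjusted p = 0.0218, and adjusted p = 0.184 with an estimated correlation. limma called 1048 probe sets, 679 higher and 369 lower, and 650 with variances without a trend. Calls numbered 460 and 424 without cellularized endosperm replicates 1 and 2, and 255 and 377 without micropylar replicates 1 and 2. Leaving out 1 of these 4 arrays ended calls of GH9B18 (adjusted p = 0.0547 without cellularized replicate 2), RCA (0.0587 without micropylar replicate 2), LHCB4.2 (0.0531 and 0.0551 without micropylar replicate 1 or 2), BAN (0.0862 and 0.0701 without micropylar replicate 1 or 2, 0.0891 without cellularized replicate 1) and PRL (0.0913, 0.227, 0.277 and 0.0953). The call of PRL also ended without either embryo array (0.0642 and 0.0638) or either whole-seed array (0.0533 and 0.0525), and in all under 11 alternatives. The other 3 photosynthesis calls ended without each of the 4 compared arrays in turn, LHCB4.1 under 8 alternatives (up to 0.282), either embryo array among them (0.0541 and 0.0538), PSBY under 6 (up to 0.234) and PSAE-1 under 5 (up to 0.172). So did the call of EXPA9 in the cell wall list (0.058 to 0.163). Of 20 genes picked by the naming rule here, 7 kept their call under every alternative: TBL45, SIM, EXPA20, EXPA4, ALDH11A3, scpl50 and ATERDJ3B. The calls of ROXY2 (4.62), XTH32 (4.41), SDT (3.65), MT1C (3.55), PLIM2a (-3.74), MYBC1 (-3.66), GSTU26 (-3.39), TUB1 (-3.33), PCME (-3.21), PHV (-2.81) and BUB3.1 (-2.75) each ended without 1 or more of the 4 compared arrays, with adjusted p from 0.0516 for PCME to 0.24 for PLIM2a. The share of calls that were higher was 64.8% as deposited, 47% with arrays scaled to equal medians and 62.9% with quantile normalization.

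The chalazal and micropylar endosperm, at opposite poles, differed by 5783 calls in limma, 2385 higher and 3398 lower in the chalazal part. With equal medians these were 3079 and 2951, a share of higher calls of 51.1% against 41.2% as deposited and 43.8% with quantile normalization. UBC31 rose by 10.71 (SE 0.76, adjusted p = 1.01e-08), from 1.95 ± 1.18 to 30093 ± 829 (n = 2 each), and by 13.38 with a pseudocount of 1 and 8.84 with 64, as the micropylar level is below the pseudocount. NET1C, an actin-binding protein gene, rose by 6.74 (SE 0.57, adjusted p = 7.38e-08), and SK16, CYP79A2, SBT4.13, RR19, AGL33, RR23, GSTU15 and PLIM2a rose by 7.81 to 5.99. BGLU29 fell by 7.99 (SE 0.45, adjusted p = 1.35e-09), to 14.8 ± 16 (n = 2), also below the pseudocount, with changes of -9.36 and -6.55 under pseudocounts of 1 and 64. EXPA4 fell by 6.30 (SE 0.60, adjusted p = 2.56e-07), and HPR, a photorespiration enzyme, fell by 6.26 (SE 0.65, adjusted p = 8.45e-07). OLEO3, SDT, SWEET11, WLIM2a, PDF2.1, AOP3 and BGLU44 changed by -7.25 to -6.14. The 9 photosynthesis genes fell (9 adjusted over the list alone), PSAN by -6.07 and PRK by -4.86, with adjusted p = 6.63e-09, and 0.0139 with an estimated correlation, and GAPDH ratios were 13.65 and 8.34 against 6.42 and 3.59, with ubiquitin ratios of 8.63 and 8.72 against 6.03 and 7.5. Cell wall loosening genes fell in 5 of 7 cases (5 adjusted over the list alone), EXPA4 by -6.30 and EXPA9 by -4.09, while ADPG1 stood at -0.39, and the call of EXPA20 ended without micropylar endosperm replicate 2 (adjusted p = 0.0678) and that of EXPA15 without chalazal endosperm replicate 2 (0.101) and without micropylar replicate 1 (0.0503). Their adjusted p was 0.0218, against 0.152 with an estimated correlation and 0.0543 with a stricter filter.

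Genes shared by all 3 endosperm parts were sought against the embryo proper and the 2 seed coat parts, with 3 compartments on each side. limma called 0 probe sets, and 707 had an unadjusted p below 0.05. None of the 11 tested lists passed: photosynthesis genes had an adjusted p of 0.813 and endosperm regulators of 0.517. In simulation this comparison called 0% of 8-fold changes, with the real differences between compartments counted as noise. The replicate block, which here fitted single arrays in place of compartment means, gave 136 calls. A contrast of group means over 14 arrays, which treats compartments as fixed, gave 3112. Both take arrays and not compartments as the replicates, as the single-compartment and pair comparisons do. The contrast had 1148 calls higher and 1964 lower in the endosperm. At 114 and 176 of these, all endosperm arrays lay beyond all arrays of the other 3 compartments. The largest named rise among them was TET4 (3.67, SE 0.35, adjusted p = 8.05e-07). Such calls hold for these compartments only.

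The maternal seed coat was compared with the 4 compartments of embryo and endosperm. TBL38 rose by 7.15 in the seed coat (SE 0.85, adjusted p = 0.0251), with 27684 ± 7456 in the general and 6371 ± 570 (n = 2 each) in the chalazal part, and was the only gene to meet the naming rule among 37 calls in limma, all 37 higher. AT3G50990, the peroxidase PER36, rose by 5.99 (SE 0.66, adjusted p = 0.0205). DFR at 5.42 and BAN at 4.62 did not pass, nor did their list (adjusted p = 0.472), though 2 of its 4 members passed adjusted over the list alone. The cell division list had adjusted p = 0.00388, with AUR2 at -3.04 and PRL at -1.75, 0 of 4 members called and 3 adjusted over the list alone, and adjusted p = 0.462 with an estimated correlation. The count was 14 and 138 with pseudocounts of 1 and 64, 17 with a stricter filter and 76 without a variance trend. It was 1037 with the replicate block and 4616 as a contrast of group means, both of which take arrays as the replicates. It was 288 without the chalazal endosperm and 0 without the micropylar endosperm. TBL38 lost its call with a pseudocount of 1 (adjusted p = 0.0509) and without the micropylar endosperm (0.0596), and AT3G50990 with a stricter filter (0.0502) and without the micropylar endosperm (0.0743).

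Whole seeds were set against the mean of the 6 compartments that they contain. WES1, a GH3 enzyme that conjugates auxin, rose by 3.75 in whole seeds (SE 0.58, adjusted p = 0.000418), with 1076 ± 21.1 (n = 2) against at most 545.3 in a compartment. ATLIG4, a DNA ligase of double-strand break repair, fell by 3.38 (SE 0.41, adjusted p = 5.01e-05), with 25.3 ± 10.9 (n = 2) against at least 243.2. ARPN, a plantacyanin, rose by 2.41 (SE 0.60, adjusted p = 0.013), and MDH by 1.53. HAT3.1, ty2 and CHR18 changed by -2.33 to -2.26, HDA15, ATSIK and MSRA5 by 1.46 to 1.41 and Phox3 by -2.33. Of 11 genes picked by the naming rule here, 2 kept their call under every alternative, WES1 and ATLIG4. Cell wall loosening genes rose in 4 of 7 cases (4 adjusted over the list alone), EXPA15 by 3.76 and EXPB1 by 2.49, while ADPG1 stood at 0.21, with adjusted p = 0.00437, and adjusted p = 0.0883 with an estimated correlation. The photosynthesis genes LHCB4.1 (1.63) and LHCB4.2 (1.28) rose, 2 of 9 (2 adjusted over the list alone), while PSAE-1 stood at 0.68 and PSBY at 0.41, with adjusted p = 0.000468, and 0.056 with an estimated correlation. GAPDH ratios, 3.2 and 2.72, were lowest here, as was the mean of the ubiquitin ratios, 5.36 and 6.25, while actin ratios were 14.81 and 9.69. limma called 1553 probe sets, 1108 higher and 445 lower, with 753 calls without whole-seed replicate 1, 434 without replicate 2 and 1015 without the chalazal endosperm. The share of calls that were higher was 71.3% as deposited, 49.7% with equal medians and 62.3% with quantile normalization. The calls of ARPN (adjusted p = 0.115 and 0.151), ty2 (0.19 and 0.148) and LHCB4.2 (0.107 and 0.124) ended without either replicate, that of LHCB4.2 also without the chalazal endosperm (0.126), and those of MDH (0.147), HAT3.1 (0.0905), CHR18 (0.0675), EXPB1 (0.0911), EXPA4 (0.332), HDA15 (0.446) and Phox3 (0.522) without replicate 2. Those of HDA15 (0.0535) and Phox3 (0.0529) also ended without a variance trend, and that of Phox3 without the chalazal endosperm (0.0589). Those of ATSIK and MSRA5 ended under 5 and 6 alternatives, among them leaving out either whole-seed array (0.228 and 0.207, and 0.288 and 0.188). That of EXPB3 ended under 6 alternatives (adjusted p of 0.0514 to 0.303), among them leaving out whole-seed replicate 1 (0.144) or 2 (0.303) and embryo proper replicate 1 (0.0514).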

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

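Every test in this part was chosen after the result was seen, apart from the array correlations and the splits of the compartments at its end. The rules of the scaling test, first read from equal medians alone, and of the RNA integrity and pool tests were changed, toward leaving them open, and the carryover and pool results were divided into parts, after their values were seen. The parts of the former were set at the markers' median, then at their upper quartile, before the shared probe sets were taken as a set. No group had 4 arrays, so single arrays were not tested against their group.

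The log2 fold change of the chalazal over the other part, the cellularized endosperm or the general seed coat, differed between endosperm and seed coat at 2811 probe sets by a test of the difference itself in limma, 1223 with a larger value in the endosperm and 1588 with a larger value in the seed coat. SWEET11 changed by -7.46 in the endosperm and by 2.47 in the seed coat (difference -9.93, SE 0.92, adjusted p = 2.99e-06), and PAP20 by 5.45 and -2.44 (difference 7.88, SE 0.80, adjusted p = 5.33e-06). At the chalazal pole 295 probe sets were called higher in both tissues and 642 lower, where independent lists would share 141.6 and 238.8, and 49 and 134 of these also passed the test of the difference, while BETA-VPE, a vacuolar processing enzyme chosen after its values were seen, rose by 3.00 and 2.88 (adjusted p = 0.923 for the difference). Across 15951 probe sets, which are not independent, the changes correlated with Pearson r of 0.308 and Spearman rho of 0.281.

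A candidate explanation for the 295 shared rises is tissue of one chalazal part in the captures of the other, tested with markers picked from these same arrays. The shared probe sets had a median level in the chalazal endosperm of 134% of the chalazal seed coat, against 3.03% for 100 seed coat markers, whose upper quartile was 18.7%, and in the other direction the medians were 74.7% and 7.67%, with an upper quartile of 13.7%. These medians, with lower quartiles of 57% and 34.9% over the shared probe sets, argue against carryover as the source of the shared rises as a set, but assign no single probe set. The directions were judged by unlike bounds on the ratio of the medians, both set after the result was seen. The stricter bound, used for the chalazal endosperm, would have been missed by 74.7% against 7.67%. In both directions the lower quartile of the shared probe sets exceeded the upper quartile of the markers. For the 34 and 35 at or below the markers' upper quartile carryover cannot be told apart from expression, since their levels overlap with those of markers, as does RR22 with 2187 in the chalazal endosperm and 18442 in the chalazal seed coat. A shared chalazal programme of both tissues stays open as a hypothesis, and the GAPDH ratios, higher in the chalazal than the cellularized endosperm, overlapped between the chalazal (6.52 and 6.38) and general seed coat (5.33 and 7.73), as did the actin ratios, while ubiquitin ratios were 9.97 and 8.76 against 10.13 and 10.39.

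Whole seeds had 1108 calls above the mean of the compartments and 445 below, and part of this may come from comparing a pool with a mean of logs: 589 of the 1108 were under 2-fold above the log of the linear mean with equal weights, while 519 were at least 2-fold above it. For these the effect of a pool cannot be told apart, since its weights are unknown. Of the 1108, 345 lay above the highest compartment mean, 39 of them by 2-fold, which no weights would give on exact, equally scaled values. These are means of 2 arrays without an error, among probe sets already called higher, with SRC2 at 3120 ± 3080 one of them. Noise and scaling could also lift a mean that far, so the counts set no bound. Scaling stays open: 49.7% of calls were higher with equal medians, which centres the changes by construction, and 62.3% with quantile normalization, against 71.3% as deposited. RNA integrity cannot be told apart either, since these probe sets shifted by 0.1 at most in the 2 groups whose arrays differ most in the GAPDH ratio, but by -0.078 to 0.158 over 6 groups. The mean ubiquitin ratio was also lowest in whole seeds (5.80) and the actin ratio was not, and seed parts that were not captured were not tested. By the naming rule the named falls lay below every compartment array, as did ATLIG4 at 25.3 against compartment means of at least 243.2. No weights of a pool would give this on exact, equally scaled values. The source of the falls was not tested, so they cannot be read as biology of the whole seed.

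A description field speaks of whole seeds for the micropylar arrays. Both arrays lay below both whole-seed arrays at 132 of 157 marker probe sets of the seed coats. Chance gives 16.7% for a single probe set. The markers were measured on the same arrays and can move together with seed coat content. That share is therefore no null for their count, and the count alone does not settle the label. It replaced a first bound, both medians under 20% of the whole-seed level. The chalazal markers missed that bound at 20.3%, while the general ones were at 8.48%. Array correlations bear on the label too. Micropylar arrays correlated with whole-seed arrays at r of 0.763 to 0.777, below the 0.873 between the whole-seed arrays and the 0.912 between the micropylar arrays. With the cellularized endosperm r was 0.808 to 0.825. These values argue against the micropylar arrays being whole seeds like those of the whole-seed arrays. BAN and DFR stood at 11.1% and 10.3% of their general seed coat level in the micropylar arrays. The 71 general seed coat markers had a median of 1.88% and an upper quartile of 5.33%. These values argue against general seed coat tissue as a whole as the source. Chalazal seed coat tissue, in which BAN and DFR were higher (1967 and 13134), was not tested as a source. An inner layer of the seed coat alone, or expression in the endosperm, could still account for BAN and DFR, and neither was tested.

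The comparison of 3 endosperm parts with 3 other compartments allows 10 splits, too few for a share under 0.05. The real split gave 0 calls and the highest other 0, so 10 of 10 gave as many. At an unadjusted p below 0.05 the split of embryo, micropylar and cellularized endosperm from the rest gave 2786 probe sets, the highest count, against 707 in the real split. That split was picked for its count and gave 0 calls, and probe sets are not independent, so no structure of the samples is read from it.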

How the results depend on the processing

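Tests without the chalazal or the micropylar endosperm were chosen after the result was seen, and the other alternatives were planned. No gene named by the rule and no called list member or list test changed direction. The balance of higher and lower calls did with equal medians: 719 and 727 in whole seeds (1108 and 445 as deposited), 516 and 582 for micropylar against cellularized (679 and 369), 3079 and 2951 for chalazal against micropylar (2385 and 3398), 3227 and 3175 in the chalazal (2516 and 3659) and 1535 and 1171 in the cellularized endosperm (1305 and 1332). With quantile normalization it turned in the cellularized endosperm (1246 and 1040) and in the chalazal seed coat (2042 and 2159, against 2164 and 2018 as deposited), which equal medians also turned (2048 and 2128). Of 182 results for genes named by the rule, 154 were called throughout as long as the chalazal and micropylar endosperm both stayed in the comparison. Among these 154, GSTU15 in the micropylar endosperm lost its call without the chalazal endosperm (adjusted p = 0.0577). With all alternatives counted, of 4337 values 4262 kept direction and call and 75 fell short, 59 of them with 1 array left out. Leaving out 1 array in turn gave 2356 to 4626 calls for the embryo proper, 1146 to 3022 for the micropylar, 1315 to 2757 for the cellularized and 4352 to 6296 for the chalazal endosperm, 2873 to 4208 for the chalazal and 1329 to 2712 for the general seed coat. It gave 1558 to 2418 for the chalazal against the general seed coat, 3660 to 5280 for chalazal against cellularized, 255 to 1202 for micropylar against cellularized and 4169 to 5984 for chalazal against micropylar endosperm. For the 3 endosperm parts it gave 0 to 0, for the seed coat 28 to 93 and for whole seeds 434 to 1688. The fits without an array have fewer samples. Other counts beyond 1.5 times, whose cause was not tested, were 1461 for the 2 seed coat parts with only the 4 compared arrays, 650 for micropylar against cellularized endosperm without a variance trend, and 1015 for whole seeds without the chalazal endosperm. The 3 endosperm parts gave 136 with the replicate block and 3112 as a contrast of group means. In the region comparisons both settings count arrays and not compartments as replicates. The seed coat gave 14 and 138 with pseudocounts of 1 and 64, 17 with a stricter filter, 76 without a trend, 1037 with the block, 4616 as a contrast of group means, 288 without the chalazal and 0 without the micropylar endosperm. Of 23 gene list calls, 8 held with an estimated correlation, all of photosynthesis, and all 23 kept direction and call under quantile normalization and equal medians. Equal medians moved the median change of all probe sets by -0.207 in whole seeds, 0.217 in the chalazal endosperm, 0.264 for chalazal against micropylar and -0.189 for micropylar against cellularized endosperm. It moved it by -0.127 in the general seed coat, 0.123 in the cellularized and -0.114 in the micropylar endosperm, and by 0.122 and -0.112 in the comparisons of the 3 endosperm parts and of the seed coat. Same-numbered arrays of different groups deviated with a mean correlation of 0.005 over 21 pairs of groups, from -0.111 to 0.146. No shared shift was seen, which does not show whether they came from the same plants. Signals near the floor limit what can be seen, as 14.61 to 20.14% of probe sets per array lay below 16.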

Other observations

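The gene sets in this part were tested after the data were seen, and 29 of 351 tests passed at the preset correlation but 0 with an estimated correlation, where the lowest adjusted p was 0.543. All 29 kept their direction under quantile normalization and equal medians. Of 69 plastid-encoded genes 51 rose in the micropylar endosperm (median 1.29, adjusted p = 1.46e-35, and adjusted p = 0.543 with an estimated correlation), among them petL by 2.73 and psbM by 2.58, on the arrays with GAPDH ratios of 6.42 and 3.59 and actin ratios of 23.59 and 10.8. In the chalazal seed coat 47 fell (median -1.12, adjusted p = 5.99e-24, and adjusted p = 0.543 with an estimated correlation), and in whole seeds, with GAPDH ratios of 3.2 and 2.72, 2 rose and 1 fell (adjusted p = 0.449). Of 14 mitochondrion-encoded genes 5 rose in the chalazal seed coat, among them nad9 by 1.27 and cox1 by 1.22 (adjusted p = 0.000651, and adjusted p = 0.543 with an estimated correlation).

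Of 8 autophagy genes 6 fell in the embryo proper, ATG8B by -4.16 and ATG8H by -2.81 (adjusted p = 0.00167, and adjusted p = 0.543 with an estimated correlation). In the chalazal endosperm 4 rose, ATG8G by 2.70 and ATG8E by 1.97 (adjusted p = 0.0121, and adjusted p = 0.559 with an estimated correlation), and 4 in the chalazal seed coat, ATG8E by 2.36 and ATG8B by 2.26 (adjusted p = 0.0298, and adjusted p = 0.616 with an estimated correlation). Of 11 IQD genes, which encode calmodulin-binding proteins, 7 fell in the chalazal endosperm, iqd32 by -5.08 and IQD28 by -4.42 (adjusted p = 0.0068, and adjusted p = 0.543 with an estimated correlation). Of 18 serine carboxypeptidase-like genes 7 rose in the general seed coat, scpl35 by 5.25 and scpl20 by 4.55 (adjusted p = 0.0312, and adjusted p = 0.543 with an estimated correlation).

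OLEO3 stood at 5405 ± 1965 (n = 2) in the general seed coat, against 16217 ± 7.92 in the embryo proper and 21.6 ± 12.5 in the chalazal seed coat. In the micropylar and cellularized endosperm it reached 17155 ± 2379 and 11319 ± 1358. Where the general seed coat signal comes from was not tested.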
